A study of Arabis alpina with 2 samples.

How the data were processed

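Libraries were made from genomic DNA of flower buds of a pool of eop055 BC1F2 plants and of the progenitor pep1-1, with 1 library per group. The number of plants in each library is not given in the sources used here. Per the submitters' processing notes, Bowtie2, SAMtools and DESeq were used. The notes give no version, role or order for them, and the genome build and the filters applied before deposit are not given in the sources used here. Each library had its own list of single-base variants, matched to its sample by the genotype in the name of the workbook sheet. Both sheet names end in the label V3_6, and that of the progenitor also carries the label V2. What these labels stand for is not given in the sources used here, so a difference in processing between the lists is not excluded. No column was left unused because it could not be matched to a sample.

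Per the file headers, each list gives the chromosome, position, reference base, the base in the sample, a column called reads, a column called quality and the allele frequency. A last column called other was not used here. The deposited allele frequency is a fraction, the alternative reads over all reads at the site. The deposited column headed reads holds values from 3.01 to 225.009 that are not whole numbers, so it was read as a Phred-scaled variant quality score. The deposited column headed quality holds whole numbers from 1 up and was read as the count of reads with the alternative base. This exchange of the headers was checked on every site: the alternative count divided by a whole number gave the listed allele frequency within 5e-05 at 14923 of 14923 pool sites and 14029 of 14029 progenitor sites. That whole number, the alternative count over the allele frequency rounded, was taken as the coverage. It was not unique at 11 pool and 6 progenitor sites, where the nearest value was used.

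Variants were matched between libraries by position and alternative base. Pool-only sites were those whose position was not listed in the progenitor with any base. Except for the overlap and the shared sites, which used all listed sites, a variant quality of at least 25 and a coverage of at least 10 were required. This left 10934 pool and 9483 progenitor sites. Markers were the pool-only G-to-A and C-to-T sites among them. Sites of the reference base have no entry in the lists, so the progenitor's depth at a pool-only position is unknown and no interval was given for it. Read counts from a pool carry the sampling of plants as well as of reads, and Wilson intervals (95%) cover the latter only. PCR duplicates, if any, were not distinguishable.

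Substitution types were compared with Fisher's exact test, two-sided, and the 2 comparisons were adjusted by Benjamini-Hochberg. The chromosome comparison used the variance over chromosomes of the median marker allele frequency, weighted by the number of markers. The window comparison used the highest median over windows of 5 Mb with a step of 1 Mb and at least 5 markers. Both were tested one-sided against 100000 permutations of the allele frequencies over the marker positions. Near-fixed markers, at 0.9 or more, were compared between chromosome 8 and all other sequences with Fisher's exact test, two-sided. Shared sites were compared one by one with Fisher's exact test on reads, two-sided, adjusted by Benjamini-Hochberg at 0.05. Such tests compare these libraries, not the genotypes at large. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

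The window test was tested on simulated data at the positions and coverages of the 1390 markers, with the highest coverages cut to a common maximum. Each pool had 100 plants, a mean of 1 crossover per chromosome and gamete, and 999 permutations. Of 40 pools with independent markers, 2 passed 0.05. Of 40 pools with linked markers and no selection, 19 passed, with a highest window median of 0.642. Of 40 pools with a selected locus all 40 passed, the highest window median was at least 0.952, and in 40 of them the locus lay in the highest window or within 2.5 Mb of it.

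Before the data were examined, a rule fixed the sites to be named: up to 20 markers of the peak window by highest allele frequency, which took all 19, and the 10 highest on all other chromosomes, with ties broken by coverage and then position. The other chromosomes were to be described by their number of markers, median and highest window, and the lowest 5 windows by count and range. The rule also named pool-only variants inside lists of floral repressor, flowering time, age pathway and branching genes. These lists were not analysed here, because the lists of variants carry no gene names and no annotation of the same build was used. Alternatives fixed at the same time changed the quality and coverage minimums, a coverage maximum, the way the progenitor was subtracted, the substitution types, the window size, marker minimum and statistic, a minimum of allele frequency, and the near-fixed threshold. Another 4 were added after seeing the data.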

Results

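Genomic DNA from flower buds of Arabis alpina, a perennial relative of Arabidopsis, was sequenced to map a mutation by its allele frequency in a pool of plants. All plants had the Pajares background. The mutant library came from eop055 plants of a BC1F2 family: the mutant line had been selfed, backcrossed to its progenitor pep1-1, selfed again, and sampled by mutant phenotype. The other library came from the progenitor pep1-1, a line that flowers without the prolonged cold that Pajares requires. Each group had 1 library and no replicate, so every test below compares these 2 libraries or positions within them and has no replicate check. The pool list held 14923 single-base variants with a median coverage of 106 reads (interquartile range 54 to 133), and the progenitor list held 14029 with a median coverage of 100 reads (36 to 139). Of these, 12922 pool sites and 12227 progenitor sites lay on the 8 chromosomes and the rest on unplaced sequences. Positions are counted from 1 at the start of each chromosome of the authors' assembly, whose build is not given in the sources used here, and genes at these positions were not analysed here. Wilson 95% intervals on allele frequencies cover counting error only.

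The progenitor comparison asked which variants of the pool were already present before the mutagenesis that made eop055. Of the pool list, 9753 sites carried the same base in the progenitor list, which was 65.4% of the pool sites (95% interval 64.6 to 66.1%) and 69.5% of the progenitor sites (68.8 to 70.3%). The pool list held 5169 positions that were not listed in the progenitor (34.6%, 33.9 to 35.4%), and the progenitor list held 4275 that were not listed in the pool (30.5%, 29.7 to 31.2%). At 1 further position, on chromosome 2, the listed bases differed, G13986849C at 0.580 in the pool and G13986849T at 0.736 in the progenitor, with a coverage of 193 reads in each. This site was named after its values were seen. Being unlisted is not the same as being absent, since a site with few reads or low variant quality is unlisted too.

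Shared variants stood at nearly the same allele frequency in both libraries. Their median was 0.487 in the pool (interquartile range 0.407 to 0.596) and 0.488 in the progenitor (0.402 to 0.620). Near-fixed alleles, those at 0.9 or more, made up 15.1% of shared sites in the pool (14.4 to 15.9%) and 15.2% in the progenitor (14.5 to 15.9%), and 1401 sites were near-fixed in both. Another 3954 shared sites, 40.5%, lay between 0.4 and 0.6 in both libraries, with a median coverage of 126 reads in the pool and 129 in the progenitor, against 70 and 69 at the sites near-fixed in both. Across sites, which are not independent replicates, the 2 sets of frequencies had a Pearson correlation of 0.920 and a Spearman correlation of 0.803. Fisher's exact test per site, adjusted by Benjamini-Hochberg, separated the libraries at 313 sites (3.21%), of which 59 were higher and 254 lower in the pool. These sites had a median pool coverage of 2550 reads, against 120 at the others, and their median absolute difference was 0.0165. The allele frequency differed by 0.3 or more at 35 of them, all lower in the pool.

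The pool-only variants were rich in G-to-A and C-to-T changes, the kind that alkylating mutagens induce. After a variant quality minimum of 25 and a coverage minimum of 10, these changes made up 1390 of 2636 pool-only sites, or 52.7% (50.8 to 54.6%). They made up 33.0% of 8298 shared sites (32.0 to 34.0%) and 21.0% of 1255 progenitor-only sites (18.9 to 23.4%). The odds ratio was 2.27 against the shared list (95% interval 2.07 to 2.48; Fisher's exact test, two-sided, adjusted p = 9.04e-73) and 4.19 against the progenitor-only list (3.57 to 4.91; adjusted p = 1.43e-81). With no quality minimum these odds ratios fell to 1.31 and 1.83. With a coverage maximum of 100 reads they were 1.57 and 5.39. Shared sites past the quality minimum, with up to 100 reads and near-fixed in both libraries, had a higher share of these changes than the pool-only list, 79.8%. Among the progenitor-only sites the leading changes were instead G-to-T and C-to-A, at 52.0% (49.2 to 54.7%), with a median allele frequency of 0.3 and a median coverage of 29 reads. The same changes made up 25.2% of pool-only sites (23.6 to 26.9%), at a median allele frequency of 0.268 and a median coverage of 39 reads, so the pool-only list also held thinly covered sites of another kind.

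**Figure D1:**
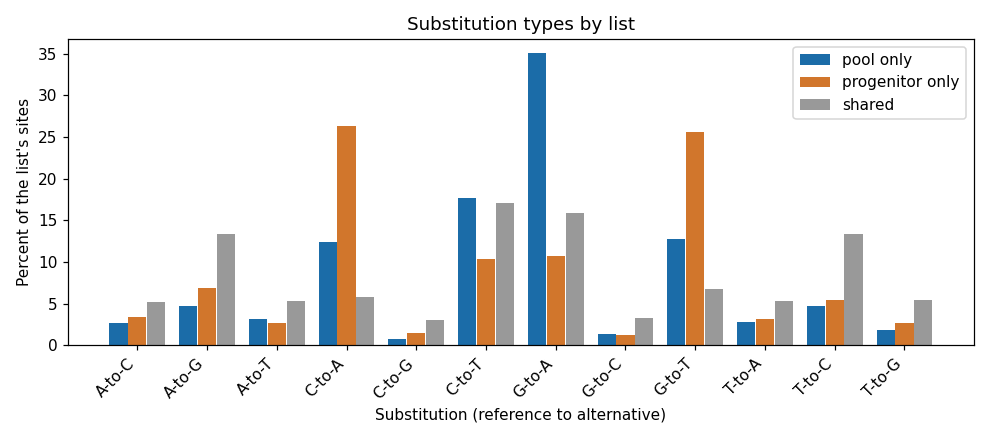
Share of each of the 12 single-base substitutions, in percent of the list's sites, among pool-only (blue), progenitor-only (orange) and shared (grey) variants past the quality and coverage minimums. G-to-A changes are the tallest pool-only bar, with 923 of 2636 sites, and C-to-A changes reach 26.4% of the progenitor-only list.

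The 1390 pool-only G-to-A and C-to-T sites served as markers of the mutagenised genome. They comprised 923 G-to-A and 467 C-to-T changes, of which 1339 lay on chromosomes and 51 on 37 unplaced sequences. Their median allele frequency was 0.491 (interquartile range 0.407 to 0.581), and 752 of them, 54.1%, lay between 0.4 and 0.6, around the 0.5 of an allele that segregates freely after a backcross and selfing. Median coverage was 67 reads (58 to 77), so the 95% interval of a single marker reached a median of 0.112 to each side. With a coverage maximum of 100 reads 1254 markers remained. Deeper markers also lay near 0.5, such as G12732120A on chromosome 2 at 0.519 with 129 reads, named after its value was seen. The shared sites between 0.4 and 0.6 in both libraries had a similar depth, so not every marker near 0.5 need be segregating.

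Chromosome 8 stood apart from the other chromosomes. Its 223 markers had a median allele frequency of 0.833 (interquartile range 0.674 to 0.878). The median was 0.553 on chromosome 1 (134 markers), 0.512 on chromosome 3 (160 markers) and 0.5 on chromosome 7 (197 markers). It was 0.459 on chromosome 5 (226 markers), 0.452 on chromosome 4 (154 markers), 0.444 on chromosome 6 (129 markers) and 0.435 on chromosome 2 (116 markers). The spread of the medians over chromosomes exceeded that of all 100000 permutations of the frequencies over the marker positions (one-sided permutation p = 1e-05, the smallest they can give). Linked markers are not independent, and in simulated pools with linkage and no selection the permutation test of windows passed 0.05 in 19 of 40 pools, so such a p shows that frequencies cluster along the chromosomes and not by itself that a locus was selected. With all substitution types as markers the median of chromosome 8 was 0.552, still the highest of the 8 chromosomes.

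**Figure D2:**
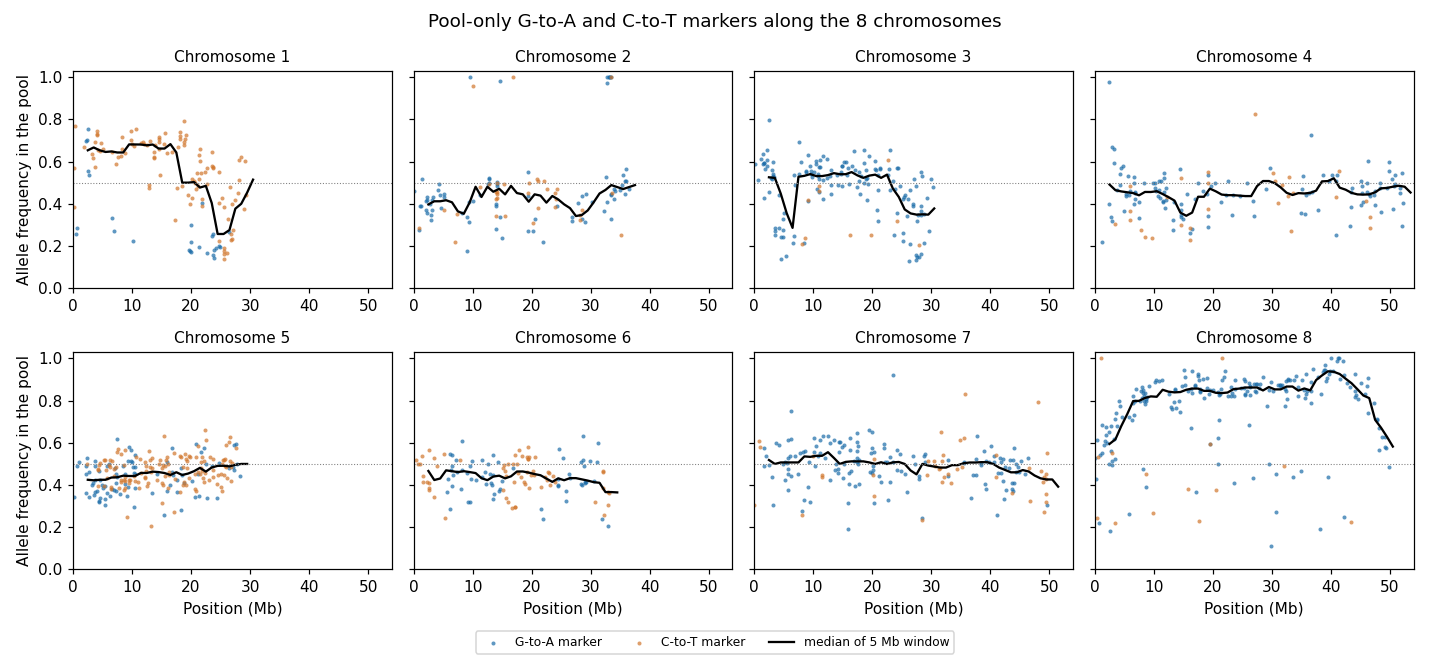
Allele frequency in the pool (vertical axis, fraction of reads) against position in Mb for each pool-only G-to-A marker (blue) and C-to-T marker (orange) on the 8 chromosomes, with the median of 5 Mb windows as a black line and 0.5 as a dotted line. The window medians of chromosome 8 reach 0.939, and no window of another chromosome exceeds 0.683.

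The mapping comparison asked where the pool approached fixation, since picking plants by the mutant phenotype enriches the causal change and those close to it. The 5 Mb window with the highest median ran from 37000001 to 42000000 on chromosome 8. Its 19 markers, all G-to-A, had a median allele frequency of 0.939 (interquartile range 0.904 to 0.959; one-sided permutation p = 0.0003), and 15 of them were near-fixed. On chromosome 8, 39 of 49 windows had a median of 0.8 or more, against 0 of 258 windows elsewhere. The highest window elsewhere lay on chromosome 1 from 14000001 to 19000000, with a median of 0.683 over 19 markers. In the simulated pools with linkage and no selection the highest window median was 0.642, which this chromosome 1 window exceeded. In the simulated pools with a selected locus the highest window median ran from 0.952 to 1, so the observed 0.939 lay below all of them. Both sets of simulated pools assumed a number of plants and of crossovers that is not known for the real pool. They also held no false calls or reads from elsewhere in the genome. The real window held markers far from fixation, G39527243A at 0.438 and G38076605A at 0.193, which lower its median. Neither comparison can therefore decide whether chromosome 1 was selected or whether chromosome 8 falls short of a selected locus. In 2 alternatives the highest window did not overlap the one from 37000001 to 42000000 on chromosome 8. With windows of 11 consecutive markers the highest median, 1, lay on chromosome 2 from 32686397 to 33504681, and with all substitution types as markers the highest window, at 0.836, was on chromosome 8 from 13000001 to 18000000.

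Within the peak window 3 changes were carried by every read. G41140691A had 70 of 70 reads (95% interval 0.948 to 1), G41352686A had 62 of 62 reads (0.942 to 1), and G40043546A had 61 of 61 reads (0.941 to 1). G41071837A, between them, had 68 of 69 reads, an allele frequency of 0.986 (0.922 to 0.997). Just outside the window lay G42099253A, with 69 of 70 reads and an allele frequency of 0.986 (0.923 to 0.997), which was named after its value was seen. These 5 sites spanned 2.06 Mb, from 40043546 to 42099253, and included every chromosome 8 G-to-A marker at 0.98 or more. The other 2 markers in that span were lower, G40349822A with 3 reference reads among 52 (0.942, 0.844 to 0.9802) and G41574114A with 5 among 52 (0.904, 0.794 to 0.958). The intervals of the 5 sites overlapped each other, so the reads did not rank them.

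The remaining markers of the peak window had lower allele frequencies, although the intervals of those above 0.9 overlapped those of the fully fixed sites. G39064926A stood at 0.967 (0.888 to 0.991), G37036328A at 0.951 (0.865 to 0.983), G39009376A at 0.944 (0.866 to 0.978) and G38781192A at 0.943 (0.846 to 0.981). G39868121A stood at 0.939, G38731498A at 0.937, G39602965A at 0.926, G37745040A at 0.913 and G39416335A at 0.905, with coverage from 49 to 69 reads. G39232229A, at 0.895 (0.806 to 0.946), and G38284381A, at 0.831 (0.737 to 0.897), missed the near-fixed threshold. The window also held 2 markers far from fixation: G39527243A at 0.438 (0.353 to 0.527), with a coverage of 121 reads, and G38076605A at 0.193 (0.124 to 0.288), with a variant quality of 28.5.

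**Figure D3:**
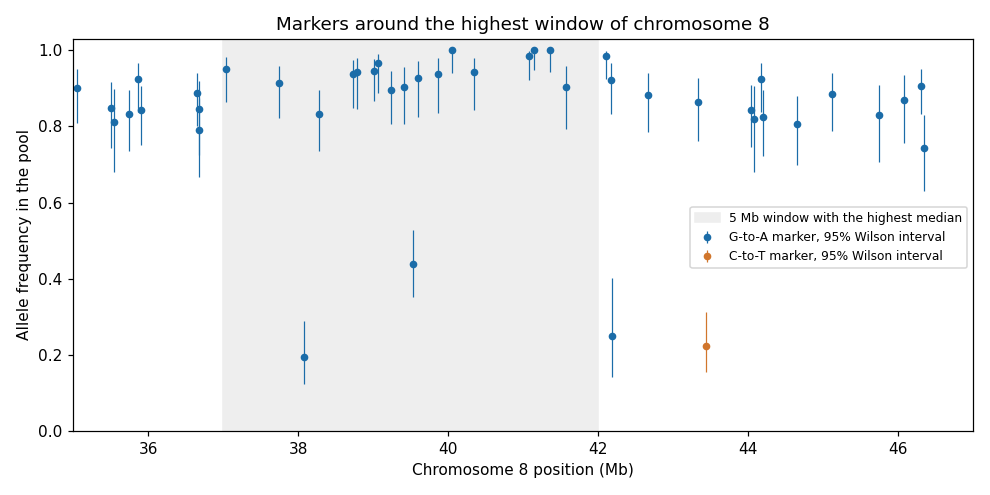
Allele frequency in the pool (fraction of reads) against position in Mb for the pool-only markers of chromosome 8 between 35 and 47 Mb, with 95% Wilson intervals as vertical lines and the highest 5 Mb window shaded. The markers at 1 or 0.986 lie between 40043546 and 42099253, and G38076605A and G39527243A are the low points inside the shaded window.

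Along chromosome 8 the allele frequency rose, levelled off, rose again and fell. In bins of 5 Mb the median was 0.595 from 0 to 5 Mb (32 markers) and 0.799 from 5 to 10 Mb (26 markers). From 10 to 35 Mb the bin medians stayed between 0.838 and 0.867. They were 0.897 from 35 to 40 Mb (22 markers) and 0.904 from 40 to 45 Mb (17 markers), and 0.709 from 45 to 50 Mb (15 markers, interquartile range 0.605 to 0.809).

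Near-fixed markers were concentrated on chromosome 8. Of 58 in all, 40 lay there, which was 17.9% of its markers (13.5 to 23.5%), against 18 of 1167 markers elsewhere, or 1.54% (0.978 to 2.43%). The odds ratio was 14.0 (95% interval 7.60 to 26.4; Fisher's exact test, two-sided, p = 2.39e-20). Chromosome 8 was picked for its allele frequencies and linked markers are not independent, so this p is too small and is not separate evidence for the chromosome. Between 35 and 43 Mb of chromosome 8, 19 of 32 markers were near-fixed. As a background measured the same way, 9 of 264 progenitor-only G-to-A and C-to-T sites were near-fixed, or 3.41% (1.80 to 6.35%), and those sites had a median allele frequency of 0.375. On the 8 chromosomes alone the background was 4 of 235, or 1.70% (0.664 to 4.29%). These sites, named after their values were seen, were G13029894A on chromosome 3 (12 reads) and C20426564T on chromosome 4 (47 reads). The others were G13010185A on chromosome 7 (6503 reads) and G11183093A on chromosome 8 (12 reads), so few of them had ordinary depth. With the threshold at 0.95 in place of 0.9, 9 of 23 near-fixed markers lay on chromosome 8, and at 0.8 the count was 135 of 157.

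Chromosome 2 held most of the highest markers outside chromosome 8. Its 11 near-fixed markers were the most on any other chromosome, although its median was 0.435. G32695143A (87 reads), G33113756A (84 reads), G33030591A (81 reads), G33348011A (71 reads), C33504681T (69 reads) and G33358681A (67 reads) were carried by every read and lay within 0.810 Mb. The stretch also held G32752327A at 0.974 and, well below it, G33399601A at 0.329, G33462447A at 0.443 and G33429444A at 0.446, which were named after their values were seen, and the progenitor list held 20 sites there. Of these, 9 had a coverage of up to 100 reads, with a median of 30, and 11 had a coverage from 525 to 2779 reads. C16816025T (83 reads, variant quality 30.5) and G9498684A (52 reads) were also carried by every read. The remaining 2 of the 10 highest sites outside chromosome 8 were G14661417A on chromosome 2, at 0.983, and G2477783A on chromosome 4, at 0.979. Their coverage of 3245 and 3583 reads was far above the median of 67.

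Windows well below 0.5 occurred as well. The 5 lowest windows had medians from 0.257 to 0.342. Of these, 3 overlapped on chromosome 1 between 22000001 and 29000000, and the others lay on chromosome 3 from 4000001 to 9000000 (0.286, 21 markers) and on chromosome 2 from 25000001 to 30000000 (0.342, 10 markers).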

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

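Of 90 values of the summary results under alternatives, 75 were classed as the same, 15 as moved, and 0 as weaker or reversed. Values classed as the same kept their direction and side of the threshold or stayed near the main value. For counts this range was wider than counting error. It took in 7564 shared sites with both minimums (main value 9753) and 1817 markers with no quality minimum (main value 1390). It also took in 84 near-fixed markers, against 58, when only progenitor sites past the same minimums were subtracted. Of the 90, 6 belong to the 4 alternatives chosen after seeing the data, which were markers of each chromosome's majority type for windows and for chromosomes, windows on the 8 chromosomes only, and near-fixed markers without the chromosome 2 stretch (51 markers). With all substitution types there were 2636 markers and 91 near-fixed, the chromosome 8 median was 0.552 in place of 0.833, and the highest window had a median of 0.836 (35 markers, permutation p = 0.00663). With windows of 11 consecutive markers it was 1 on chromosome 2 (permutation p = 1e-05), where those markers lie within less than 5 Mb. All other window alternatives kept a peak on chromosome 8, and 2 Mb windows placed it from 40000001 to 42000000 (0.993, 6 markers). Near-fixed markers numbered 98 with no quality minimum, 157 at a threshold of 0.8 (135 on chromosome 8) and 23 at 0.95 (9 on chromosome 8). Their odds ratio for chromosome 8 ran from 3.46 to 79.8. With both minimums applied, shared medians were 0.496 in the pool and 0.497 in the progenitor, and near-fixed shares 15.9% and 16.0%. At a threshold of 0.8 these shares were 17.1% and 17.4%. Where not stated, the cause was not tested. The spectrum odds ratio ran from 1.31 to 3.003 against shared and from 1.83 to 5.45 against progenitor-only sites, lowest with no quality minimum and highest with a quality minimum of 35. Of the 29 named sites, 4 were lost at a quality minimum of 35 and 3 at a coverage maximum of 100. No paired analysis was possible because each group had 1 library, and no replicate could be left out. Depth limits the interval of a single marker to a median of 0.112 on each side.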

Other observations

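All tests in this part were chosen after the results were seen, as were the bounds of the stretches, and 4 were revised after a first outcome: those for missed calls on chromosome 2, whose earlier coverage limit would have argued against them, for a selected locus on chromosome 2, for collapsed repeats and for differences within the progenitor stock.

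Fixed sites shared by both libraries were mostly of the G-to-A and C-to-T kind on chromosomes 2 and 8, and to a lesser share on all other sequences together. Of 779 sites past the quality minimum, with a coverage of up to 100 reads and near-fixed in both libraries, 622 were of these types, or 79.8% (95% interval 76.9 to 82.5%), with 223 G-to-A and 399 C-to-T. The share was 93.1% on chromosome 8 (89.9 to 95.4%) and 92.0% on chromosome 2 (87.8 to 94.8%), against 92 of 207 sites, or 44.4% (37.8 to 51.3%), on all other sequences together. These other sequences include the unplaced ones, so the 44.4% is not a share for chromosomes alone. Chromosome 8 held 312 of the 622, of which 302 were C-to-T and 10 G-to-A, between 220858 and 48363582. Its pool-only markers were mainly of the opposite kind, 209 G-to-A and 14 C-to-T. Chromosome 2 held 218, of which 168 were G-to-A and 50 C-to-T. On chromosome 7 they made up 30 of 44 such sites (68.2%, 53.4 to 80.0%) and on chromosome 4 33 of 57 (57.9%, 44.98 to 69.8%), and each of the other chromosomes held at most 5. Whether these sites arose in the progenitor line or are differences of its background from the assembly was not tested.

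On chromosome 1 the marker types differed in allele frequency in neighbouring bins of 5 Mb. From 15 to 20 Mb, 5 G-to-A markers had a median of 0.179 and 18 C-to-T markers a median of 0.681. From 20 to 25 Mb, 11 G-to-A markers had a median of 0.193 and 24 C-to-T markers a median of 0.532 (permutation p = 2e-05, two-sided, for a bin chosen after the values were seen), with a median coverage of 71 and 62 reads and a median variant quality of 114 and 200. Of these, 10 of the G-to-A markers and 1 of the C-to-T markers, C24732525T, lay below 0.3. The few G-to-A markers from 5 to 10 Mb (2 markers, 0.302) and from 10 to 15 Mb (1 marker, 0.224) also lay below the C-to-T medians there, 0.658 and 0.679. From 0 to 5 Mb the medians were 0.554 for 7 G-to-A and 0.660 for 14 C-to-T markers. From 25 to 30 Mb the 22 C-to-T markers were lower themselves, with a median of 0.380 and quartiles of 0.229 and 0.450. They lay beside a lone G-to-A marker at 0.265. Low C-to-T markers, such as C25516756T at 0.139, lay among higher ones, such as C25575748T at 0.384. Low frequency in that bin was thus not tied to 1 marker type. These sites were named after their values were seen.

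In 3 short stretches, fixed sites of the pool and of the sequenced progenitor disagreed. On chromosome 3 from 29621658 to 30197310, 15 sites had a median of 1 in the progenitor and 0.518 in the pool. On chromosome 7 from 50007625 to 50425788, 6 sites had medians of 1 and 0.5. On chromosome 2 from 32695143 to 33504681, 7 sites near-fixed in the pool were unlisted in the progenitor. The sites of chromosomes 3 and 7 were picked by these values, at 0.9 or more in the progenitor and below 0.7 in the pool. The size of their difference is therefore partly set by that choice. Of 22 G-to-A and C-to-T sites picked so with up to 100 reads in each library, 1 lay outside these 2 stretches. Collapsed repeats are argued against by a median pool coverage only 1.04 times that of all markers over the 28 sites, taken with no coverage maximum, and a further selected locus on chromosome 2 by the 10 markers within 2 Mb on either side, whose median was 0.455 (bootstrap 95% interval 0.394 to 0.476). A missed progenitor call on chromosome 2 cannot be told apart from a real difference, because the progenitor's depth at those 7 positions is unknown. The 9 progenitor sites listed there with up to 100 reads had coverages from 8 to 45, so sites of such depth could be listed. The other 11, at 525 or more, do not give the depth of single-copy sequence. Whether plants of the progenitor stock differed in inherited stretches on chromosomes 3 and 7 stays open too. There 21 of 21 sites were G-to-A. At the G-to-A share of those chromosomes' markers, 0.938 and 0.777, that has a chance of 0.0834 if sites are independent. Neighbouring markers shared their type more often than that, and the shares are those of pool-only markers, so this chance cannot decide the question. A mixed or mislabelled seed lot was not tested.

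G-to-A and C-to-T markers clustered by type along the chromosomes, without separating fully. Neighbouring markers were of the same type in 80.4% of 1331 pairs, against a mean of 68.0% after shuffling types within chromosomes (permutation p = 1e-05, the smallest that 100000 shuffles can give), and the highest shuffle reached 72.1%, which argues against false calls scattered at random as the whole list. Mutagen damage on 1 DNA strand of each inherited stretch may account for part of it, since that would give runs of 1 type. Mixed bins also occurred, such as chromosome 5 from 5 to 10 Mb, with 27 G-to-A and 31 C-to-T markers. The order of the types within such bins was not examined. On chromosome 8 the 14 C-to-T markers had a median allele frequency of 0.418, against 0.836 for the 209 G-to-A markers (permutation p = 2e-05, two-sided), although C1121957T and C21542878T were carried by every read. The 14 C-to-T markers had a median variant quality of 36.5, against 215, so reads from elsewhere in the genome and false calls both stay open for them.

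The allele frequency of chromosome 8 stayed near 0.85 from 10 to 35 Mb, with a median of 0.851 over 111 markers. Unselected plants in the pool as the whole cause are argued against by 7 markers of the peak window whose lower limits lay above that level. That window was picked for its high allele frequencies, and the limits cover the sampling of reads only. The count of 7 may therefore overstate this evidence. Few crossovers, alignment bias against the alternative base and the order of sequences in the assembly were not tested and stay open. Sites fixed for the alternative base, whose frequency such a bias leaves at 1, cannot show it.

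Unplaced sequences held 34 pool-only markers with a coverage of up to 100 reads, and 6 of them (17.6%) stood at 0.8 or more, against 5 of 20 progenitor-only sites (25%). Of those 5, 4 lay on scaffold_740, and without that sequence the background was 1 of 12 (8.33%). That sequence was left out after its values were seen, with no like removal among the pool sites. The direction of the comparison depends on this choice, so it stays open. The 6 pool sites had coverages from 11 to 74 reads. The most deeply covered of the 6 was G31097A on scaffold_281, with 70 of 74 reads (0.946, 95% interval 0.869 to 0.979).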
